A study of Drosophila melanogaster with 2 samples.

How the data were processed

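The series holds 2 Agilent oligonucleotide arrays with 22575 spots each, on which RNA of sorted stage 4 pole cells and RNA of whole stage 4 embryos were hybridised together with the dyes swapped. Per the labels' protocols, pole cells were isolated by FACS through an EGFP-Vasa transgene, whole embryos were homogenised, and 100 ng of total RNA was labelled with Agilent's linear amplification for small RNA amounts. The labels do not say whether the embryos homogenised whole carried the transgene or went through any step of the sort. The channel that held each RNA was taken from the dyes in the labels, and every ratio was turned to pole cells over whole embryos.

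The deposited scanner tables were made with Agilent Feature Extraction A.7.1.1, per the file headers. They hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in each channel, which are not normalized, and processed intensities that the software had corrected for background and for dye by LOWESS on rank-selected probes, with surrogate values for signals not above background. The deposited log10 ratio of red over green is computed from these processed intensities, per the file headers. Flags of 0 or 1 for outlier, saturated and well above background spots were set by the same software. A value table deposited by the authors holds 1 more column per array with no stated scale. Set against the scanner files, its column for the array with pole cells in Cy3 had a slope of 2.27 on the log10 ratio of pole cells over whole embryos (r = 0.938 over probes, 0.999 over those well above background in both channels), close to the 2.30 that a natural log would give. The column of the other array gave a slope of 1.54 with r = 0.655 (1.83 and 0.821 above background), which does not settle its scale. The SD of its values was 2.35 times that of the log10 ratio (2.23 above background). These deposited natural log values were read as pole cells over whole embryos in both columns, on the slope of the first. The columns' medians were 0.028 with pole cells in Cy3 and 0.025 with pole cells in Cy5, their lowest value was -4.61, and their normalization stays unknown.

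From the mean intensities, background was corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess, with control and outlier spots at weight 0, in limma 3.58.1 (R 4.3.3, jsonlite 2.0.0). Outlier spots were left out after that (225 probes on either array, 200 of them on the array with pole cells in Cy5 and 31 on the other), and saturated spots were kept. A gene was represented by its brightest probe measured on both arrays, and was tested if this probe was well above background in at least 1 RNA on both arrays. That gave 11486 genes. On both arrays, 9948 were well above background in both RNAs, 1504 in pole cells only and 34 in whole embryos only. In Cy3, 70.6% of probes were so for whole embryos, the dimmest channel, and 83.0% for pole cells. In Cy5 it was 96.3% for whole embryos and 95.2% for pole cells. These counts therefore do not compare the numbers of transcripts in the RNAs. For 5315 genes several probes were above background. Of the genes past the size rule, 136 had several such probes, and 10 had probes of opposite sign. Among the genes not past it, 129 had another probe with a mean log2 ratio of at least 1 in size. The offset draws the log ratios of dim probes toward 0. Gene tables, random lists and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

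Probes carry the gene numbers of the array's design. Of 13693 such numbers, 11717 matched a locus tag of the RefSeq gene table (assembly Release 6 plus ISO1 MT) and 1129 a synonym of 1 gene, which gave current symbols. Another 203 were synonyms of several genes and 644 had no match, and these kept their numbers. The assembly behind the array is not given in the sources used here, so no coordinates are printed. List members were matched in the same way, with nos read as nanos and Ald as Ald1 by their gene numbers.

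Both arrays were treated as 1 replicate, so genes were counted by size and the main analysis used no p-value: a gene was higher or lower if its log2 ratio was at least 1 in size and in the same direction on each array. Named genes, by a rule fixed before the data were examined, were the 15 highest and 15 lowest with a symbol that met the size rule and were well above background in both RNAs, the 5 highest and 5 lowest without a symbol, the 4 members of each gene list with the largest mean log2 ratio in size, all measured members of the germ plasm list, the 5 largest at-least folds in each direction, and vas as the sort marker. For a gene not well above background in 1 RNA on both arrays, the at-least fold sets the bright RNA's mean against the dim RNA's mean of, per array, the higher of the lowest signal among probes well above background and its own, on log2 channel values after loess and Aquantile. This applied to 3 genes in whole embryos, of which 2 had a bound above 1, and to 0 in pole cells.

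The 21 gene lists were also fixed before the data were examined, from general knowledge of fly embryology, and 5 more were written after the results were seen. For each list the median log2 ratio was set against 10000 random lists of the same size matched in 20 bins of average signal, as a description of these arrays. Some members were not found on the array by name, among them pgc, mt:lrRNA, spn-E, squ, del, ind, Hsp70Ba and Hsp22. Outlier spots removed 29 of the cytoplasmic ribosomal protein genes, 3 proteasome genes, 2 mitochondrial ribosomal protein genes and slam. Apart from the lists, outlier spots also removed 2 genes that would have met the size rule with such spots kept, Tao (log2 2.16) and CG3107 (1.60), both named after their values were seen.

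The procedure was tested on simulated scanner files with 10921 genes for the same comparison, with 50 genes changed at each of 4 sizes. It found in the true direction 2.0% of genes changed by a log2 ratio of 1, 42.0% at 1.5, 56.0% at 2 and 84.0% at 3, with median measured sizes of 0.68, 1.11, 1.21 and 1.76, 0 genes in the wrong direction and 0 of 10721 unchanged genes. Of 200 random lists 12 lay outside the middle 95% of random medians, and all 200 lists shifted by 0.5 lay above it. That shift was added to the finished log ratios, so lists changed in the scanner signals were not tested. The background noise of the simulation was set after a first run, to match the negative control spots of the array with the steadier background. The other noise was a fixed log2 SD of 0.15 per spot and channel, and no dye effect of single probes was simulated. The count of unchanged genes found therefore holds only for that noise. The alternatives tried were other background corrections, median centring, the value table, other filters, the mean of all probes, outlier spots kept, saturated spots left out, each array alone, other size rules, limma with the arrays as separate replicates, random lists without matching, means of lists and, chosen after the data were seen, removal of a smooth trend across the slide (loess surface, span 0.3).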

Results

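Pole cells are the primordial germ cells of Drosophila melanogaster. They bud off at the posterior pole, and at stage 4 they sit outside the syncytial layer of nuclei that will form the body. Per the labels, pole cells were sorted by fluorescence from embryos that carried EGFP fused to Vasa, a germline RNA helicase, and embryos of the same stage were homogenised whole. Both RNAs, 100 ng of total RNA each, were amplified, labelled and hybridised together on 2 Agilent oligonucleotide arrays. Pole cell RNA carried Cy5 on 1 array and Cy3 on the other. The titles of both arrays carry the number 1, so the pair was taken as 1 replicate measured in both dye orientations, although the labels do not say whether the extracts were the same, and no significance test of pole cells against whole embryos was possible. Ratios are pole cells over whole embryos, and the SD after a log2 ratio is that of its 2 orientations, taken as a technical spread.

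Each array held 21924 different probes for genes. Pole cell RNA gave signals well above background at 95.2% of them in Cy5 and at 83.0% in Cy3. Whole embryo RNA did so at 96.3% in Cy5 and at 70.6% in Cy3. Median brightness above the local background was 121 units for pole cells in Cy5, 42.9 for pole cells in Cy3, 199.8 for whole embryos in Cy5 and 25.7 for whole embryos in Cy3. Saturation affected 3 probes for pole cells and 14 for whole embryos, all in Cy5. The number of arrays limits the precision of every ratio.

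The comparison asked which transcripts are enriched in the early germ line relative to the embryo as a whole. With the offset of 50, the highest ratio belonged to nanos, the translational repressor of the posterior pole, at 10.2-fold (log2 3.35 ± 0.48). Next among genes with a symbol came shu, a cochaperone needed for piRNA biogenesis, at 8.41-fold (log2 3.07 ± 0.09), and the inducible chaperone genes Hsp70Ab at 7.38-fold (log2 2.88 ± 1.07) and Hsp68 at 7.32-fold (log2 2.87 ± 0.84). The top rank depended on the processing: with an offset of 0, Hsp70Bc (log2 3.88) and Hsp68 (3.87) lay above nanos (3.72), as they did with the software's log ratio or processed values and in the value table. For Hsp70Bc the whole embryo signal was not well above background on both arrays, so its exact ratio and rank are uncertain. With the offset of 50, the lowest ratio belonged to gus, whose product binds Vasa, at 9.40-fold lower (log2 -3.23 ± 0.13), followed by the insulator gene BEAF-32 (log2 -2.91 ± 0.30), the boundary factor gene Elba3 (log2 -2.77 ± 0.08) and the anterior determinant bcd (log2 -2.70 ± 0.67). In the value table bard was below gus. Of 11486 genes tested, 64 were higher and 115 lower by a log2 ratio of at least 1 on each array, so that 35.8% of these genes were higher. The counts rose to between 132 and 156 higher and between 258 and 282 lower with an offset of 0, with the software's processed values or log ratio, or with the value table, and to 166 and 333 with an offset of 0 and a trend across the slide removed, an alternative chosen after the data were seen. They fell to 34 and 33 (50.7% higher) with median centring in place of loess, and to 45 and 57 with the mean of all probes of a gene.

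**Figure D1:**
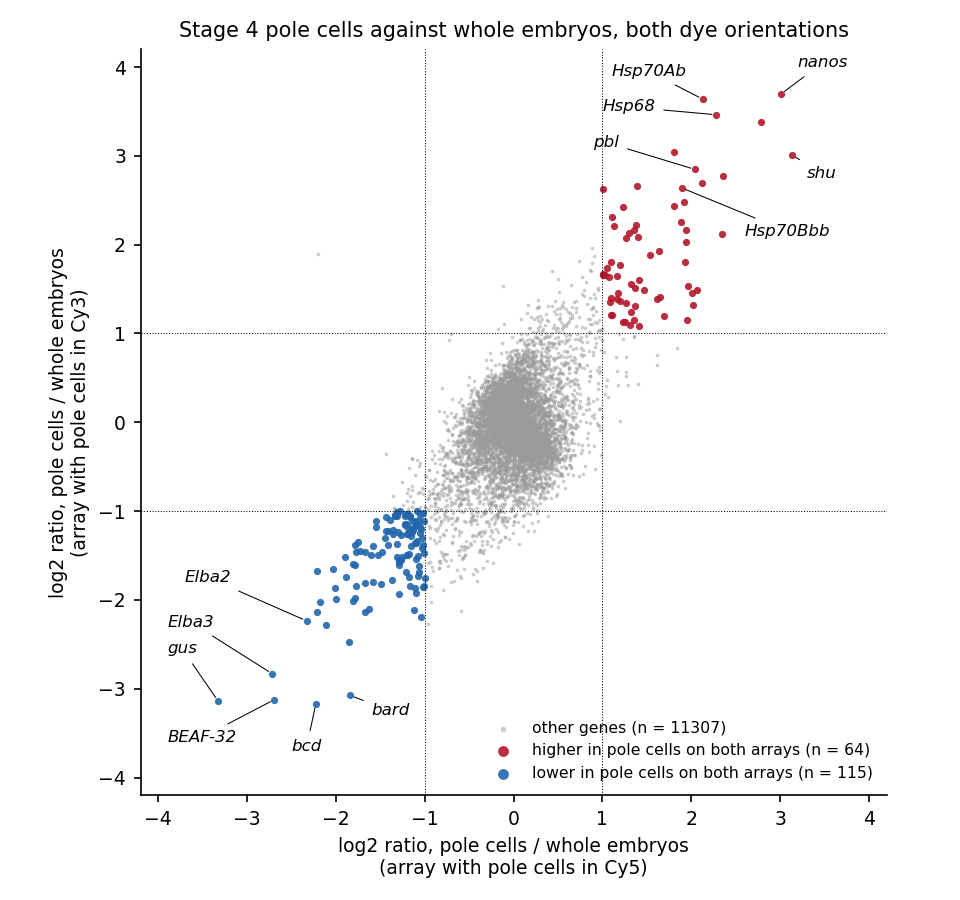
Log2 ratio of pole cells over whole embryos for 11486 genes (points) on the array with pole cells in Cy5 (x axis) and on the dye-swapped array (y axis), with dotted lines at a log2 ratio of 1 in either direction. The 64 genes in red were past 1 on both arrays, nanos among them at 3.01 and 3.70, and the 115 genes in blue were past -1 on both, with gus at -3.33 and -3.14.

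Among the 15 highest with a symbol, besides nanos and shu, were gcl, a nuclear envelope factor needed for pole cell formation (log2 1.98 ± 0.06), and Tre1, a receptor that guides germ cell migration (log2 1.77 ± 0.41). They also held pbl, a RhoGEF of the contractile ring, at 5.44-fold (log2 2.44 ± 0.57), Nin, the ninein homologue, at log2 2.20 ± 0.40, and Cen, the centrocortin gene, at log2 1.87 ± 0.09. The others were RapGAP1 (log2 2.12 ± 0.45), the Mediator subunit gene MED26 (log2 2.05 ± 0.16) and the heat shock genes Hsp70Bbb (2.27 ± 0.53), Hsp70Bb (2.07 ± 0.26), Hsp70Aa (2.03 ± 0.90) and Hsp23 (1.78 ± 0.21). Without a current symbol, 15 of the 64 genes are known by number, led by CGX0067 (log2 3.08), CG13380 (2.56), CG12112 (2.40), CG5292 (2.23) and CG17658 (1.83). Of the 64, 61 were well above background in both RNAs on both arrays. In the other 3, Hsp70Bc, Taf12L and CG10445, whole embryo RNA was so on 1 of the 2 arrays. The median log2 ratio of the 64 genes was 1.67.

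Among the 15 lowest with a symbol were Elba2, which encodes another subunit of the Elba boundary complex (log2 -2.28 ± 0.07), smg, the Smaug regulator of maternal mRNA (-1.94 ± 0.38), and Delta, the Notch ligand (-1.94 ± 0.10). Further members were the CBF-beta homologue Bro (-2.17 ± 0.06), the histone acetyltransferase adaptor Ada2b (-1.91 ± 0.33), Chrac-16 of the chromatin accessibility complex (-1.86 ± 0.34) and the general factor TfIIFbeta (-1.85 ± 0.27). The set was completed by bard (-2.46 ± 0.87), the S-adenosylmethionine synthetase gene Sam-S (-1.99), the scaffold gene Liprin-alpha (-1.91 ± 0.14) and crok (-1.82 ± 0.10). By number, 32 of the 115 lower genes had no symbol, led by CG5180 (-2.20), CG15382 (-2.16), CG14915 (-2.10), CG18269 (-1.88) and CG5568 (-1.81). All 115 were well above background in both RNAs, and their median log2 ratio was -1.37. For 9 of the 30 genes named as highest or lowest, probes of the gene lay over 1 apart: another probe of Nin went in the other direction, another gave 0.01 for RapGAP1, -0.28 for bcd and -0.04 for Sam-S, and such probes also existed for smg, Delta, Ada2b, Liprin-alpha and crok.

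Maternal mRNAs localised to the germ plasm were higher in pole cells as a group. All 13 measured members of the list had a mean log2 ratio above 0, with a median of 1.01, above all 10000 random lists matched on signal. The size rule was met by 5 of them, namely nanos, gcl, CycB, the mitotic cyclin (log2 1.75 ± 0.31), ovo, a germline transcription factor (1.71 ± 0.25), and Hsp83, the Hsp90 gene (1.24 ± 0.21). The values of the others were 1.34 for exu, 1.01 for spir, 0.93 for zpg, 0.70 for orb, 0.69 for bru1, 0.58 for sra, 0.48 for osk and 0.32 for aub. Another probe gave 0.04 for exu, -0.06 for spir, 0.04 for orb and 0.09 for bru1, while another of CycB gave 2.94. The heat shock list, whose median was 2.03, was higher in the same sorted RNA. vas, on which the sort was based, had a log2 ratio of 0.17 ± 0.46 and is no finding.

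Genes of the germline piRNA pathway and nuage had a median log2 ratio of 0.16, at the 99.9th percentile of matched random lists, with values of 0.10 and 0.33 on the single arrays. Of 18 measured members only shu was higher by the size rule and only papi, a Tudor domain gene, lower (-1.50 ± 0.48), while zuc gave 1.39 and armi 0.72. Among 18 maternal mRNA regulators, pum, the partner of nanos in repression, was higher (1.67 ± 0.50) and smg lower, with cup at 1.04 and pAbp at 0.87. Their median of 0.08 lay at the 90.2nd percentile of matched lists and at the 99.5th of lists drawn without matching, but its sign differed between the arrays, at 0.35 with pole cells in Cy5 and -0.10 with pole cells in Cy3.

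Of the 16 maternal body axis genes, bcd and pll, a kinase of the Toll pathway (log2 -1.49 ± 0.54), were lower, and ea and spz of the same pathway gave -1.01 and 1.09. The list's median of -0.08 lay at the 8.99th percentile of matched lists and at the 1.47th of unmatched ones. None of the 19 gap, head and terminal genes met the size rule, and tll, a terminal gap gene, gave 1.29, hb -1.03, D -0.59 and slp1 -0.53 (median -0.04, 3.89th percentile). None of the 12 pair-rule and segment polarity genes did so either, with ftz at -0.53, eve and hry at -0.11 and opa at 0.11 (median -0.01, 18.5th percentile). With an offset of 0 in place of 50, 1 gene of the gap, head and terminal list was higher and 1 lower by the size rule. The 31 dorsoventral genes had a median of 0.04, at the 98.1st percentile of matched lists and the 96.6th of unmatched ones, and their median was 0.29 in the authors' value table. In that list scw, a BMP ligand gene (log2 -1.23 ± 0.19), and tsg, which encodes a BMP binding protein (-1.02), were lower, while wntD gave 1.14, ush 1.11 and peb 1.05. With an offset of 0, 4 dorsoventral genes were higher and 2 lower by the size rule. Hox genes were near 0, from 0.01 for Scr to 0.08 for Antp (0.06 for Dfd, 0.04 for Abd-B and 0.03 for lab), with a median of 0.04 over 6 members (85.0th percentile).

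Early zygotic genes of the cellularising blastoderm were lower in the median but not in every member. The 10 measured members had a median log2 ratio of -0.59, below all 10000 matched random lists, with -0.34 and -0.72 on the single arrays. The size rule was met by 3, namely halo, which acts in lipid droplet transport (-1.43 ± 0.59), nullo, which acts at the forming furrows (-1.19 ± 0.20), and term (-1.14 ± 0.20), while sala gave -0.89. In 2 of the 10 the mean log2 ratio was above 0, at 0.77 for Sry-alpha and 0.39 for Ama. For bnk it was -0.04, although another of its probes gave -1.65. All of these were named after their values were seen. With the mean of all probes of a gene the list's median was -0.86. With outlier spots kept, slam was measured too (-2.29) and the median was -0.87. The 8 sex determination counting genes had a median of -0.32 (0.03rd percentile), and none met the size rule with the offset of 50. With an offset of 0, 3 of them were lower by that rule and the median was -0.55. Their lowest values were -0.90 for da, -0.88 for dpn, -0.68 for upd1 and -0.40 for Sxl, and their medians were -0.09 and -0.57 on the single arrays.

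Heat shock genes were the group with the highest median, 2.03, above all 10000 matched random lists and 4.07-fold on the linear scale. Of 11 measured members 7 met the size rule: 5 Hsp70 copies, including Hsp70Bc (2.43 ± 0.87), with Hsp68 (2.87 ± 0.84) and Hsp23. Hsp27 gave 0.55, DnaJ-1 0.54, stv 0.11 and Hsp26 -0.01. The Hsp70 copies are nearly identical, so their probes are not independent measurements. None of 11 immediate early, JNK and apoptosis genes met the size rule (median 0.01, 67.4th percentile), with egr, a TNF ligand gene, at 0.62, puc at -0.20, skl at 0.16 and Jra at -0.14, while 1 of them did so with an offset of 0. The labels describe sorting for pole cells only, so effects of sorting and of cell type cannot be told apart.

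Lists of core cellular machinery had medians close to 0, which differed in sign between the arrays for both ribosomal protein lists and the proteasome. Of 60 measured cytoplasmic ribosomal protein genes RpL7A was higher (log2 1.20 ± 0.15), sta gave 0.99, RpL5 -0.76 and RpL38 -0.56, and the median was -0.09 (8.74th percentile). The 67 mitochondrial ribosomal protein genes had a median of -0.06 (4.34th percentile), with mRpS18A at -1.14, mRpL12 at 0.62, mRpL21 at -0.48 and mRpS25 at -0.41. Oxidative phosphorylation genes had a median of -0.05 over 80 members (2.31st percentile), which was 0.02 with median centring, and their extremes were ND-MLRQ at -0.50, ND-24 at 0.50, ND-AGGG at -0.48 and SdhD at -0.47. The median was 0.03 for 38 proteasome genes (92.3rd percentile), with Prosbeta4 at 0.69, Rpn7 at 0.66, Prosbeta1 at -0.62 and Rpn9 at 0.61. It was -0.11 for 12 glycolytic genes (15.9th percentile), with Eno at 0.84, PyK at 0.76, Pgi at -0.62 and Tpi at -0.58. Without matching on signal, the lists of cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins and glycolysis lay at the 0th, 0.01st and 1.70th percentiles. Of 19 cell cycle genes CycA (-1.42 ± 0.19) and CycD (-1.21 ± 0.18) were lower, pim gave -0.84 and Wee1 0.74, and the median was -0.05 (27.2nd percentile).

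Markers of other material showed no member past the size rule, which does not decide whether such material was present. The offset draws dim log ratios toward 0, and 0 genes in the dimmest of 3 equal groups by average signal met the rule. Limits of matched random medians were also narrow, at -0.04 to 0.06 for the yolk protein and follicle cell list and -0.03 to 0.04 for the muscle, nerve and blood list. The 9 measured yolk protein and follicle cell genes had a median log2 ratio of 0.02 (64.3rd percentile), with psd at 0.11, Cp38 at -0.09, Yp2 at 0.07 and Yp3 at 0.06. The 19 measured muscle, nerve and blood genes had a median of 0.03 (91.4th percentile), with crq at 0.49, Act87E at 0.27, Act57B at 0.16 and Mlc2 at -0.13. Housekeeping genes had a median of 0.17 over 9 members, at the 93.7th percentile of matched lists and the 99.7th of unmatched ones, but it was -0.02 with pole cells in Cy5 and 0.36 with pole cells in Cy3. Their largest values were alphaTub84B at 0.47, betaTub56D at 0.38, Tbp at 0.36 and Act5C at -0.35. Of the genes not well above background in whole embryos on both arrays, only lncRNA:noe, at least 1.26-fold higher in pole cells, and upd2, at least 1.05-fold higher, had a bound above 1. Their log2 ratios with pole cells in Cy5 and in Cy3 were 0.09 and 0.65 for lncRNA:noe and -0.02 and 0.30 for upd2, so that upd2 was not higher in both orientations.

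**Figure D2:**
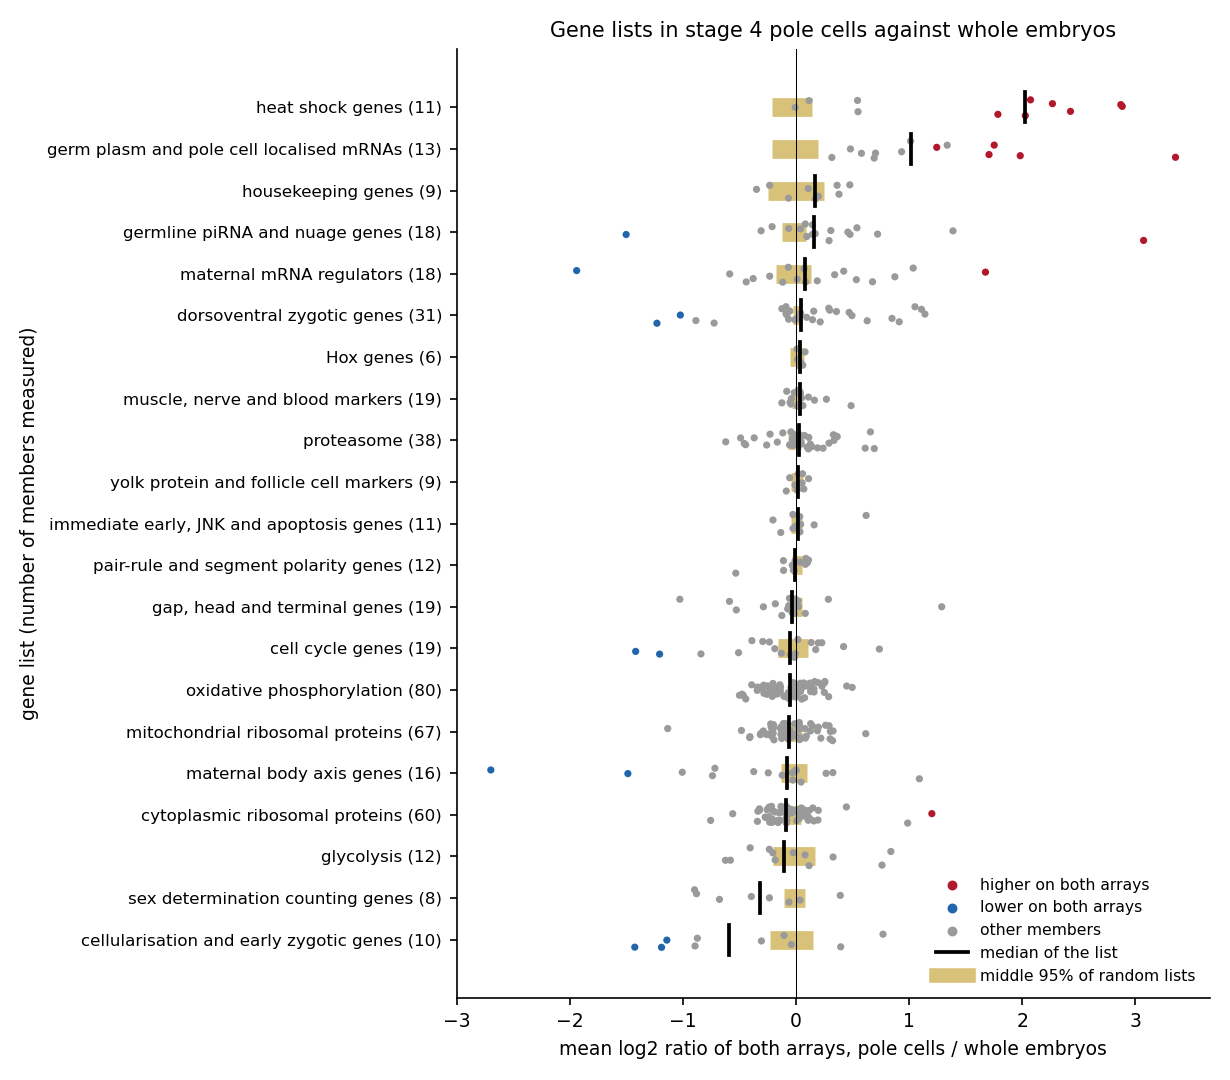
Mean log2 ratio of both arrays, pole cells over whole embryos, for each measured member (points) of the 21 gene lists, with the list's median (black bar) and the middle 95% of medians of matched random lists (yellow band). The medians of the heat shock list (2.03) and the germ plasm list (1.01) lay to the right of their bands, and that of the cellularisation list (-0.59) to the left.

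The orientations of the dye swap correlated at r = 0.493 across the 11486 genes, which are not independent replicates. The same sign on both arrays was found for 40.0% of genes, and the median SD of the orientations was 0.178 for all genes and 0.194 for those past the size rule. With genes in 3 equal groups by average signal, r was -0.218 in the dimmest, 0.493 in the middle and 0.554 in the brightest, which held 0, 48 and 131 of the genes past the size rule. A single gene number, CGM1001, named after its values were seen, was past 1 in opposite directions, at -2.21 with pole cells in Cy5 and 1.89 with pole cells in Cy3. Log ratios changed smoothly across the slide, in opposite directions once both were expressed as pole cells over whole embryos. With that trend removed r was 0.81, a rise that removing opposite trends brings by construction, and the counts were 71 higher and 121 lower, of which 64 and 105 were the same genes. With median centring in place of loess r was -0.46.

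**Figure D3:**
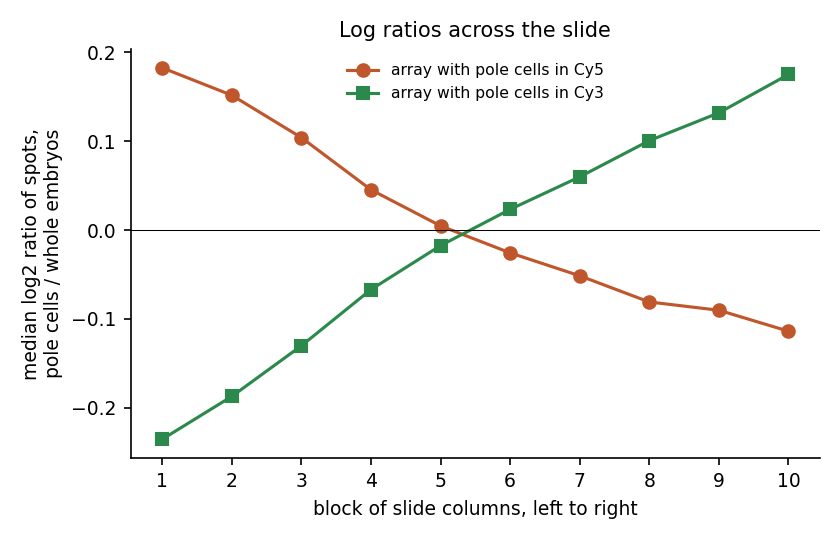
Median log2 ratio of spots, pole cells over whole embryos (y axis), in 10 successive blocks of the slide's columns (x axis) for the array with pole cells in Cy5 (circles) and the array with pole cells in Cy3 (squares). The median went from 0.18 to -0.11 on the first and from -0.24 to 0.18 on the second.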

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

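All alternatives were chosen before the data were examined except the removal of the slide trend with either offset, which was chosen after the trend was seen. Each ratio already compares both RNAs on the same array. No analysis across replicates was possible because both arrays carry the replicate number 1, although the labels do not say whether they held the same extracts. The main counts were 64 higher and 115 lower genes and the dye-swap r was 0.49. They gave 138, 258 and 0.31 with the Feature Extraction log ratio, 134, 264 and 0.31 with its processed signals and loess, 132, 260 and 0.33 with an offset of 0, and 156 and 282 with the value table. Median centring gave 34 and 33 genes with r turned to -0.46, and array medians of 0.316 and -0.275. Without background subtraction r was 0.39. The mean of all probes gave 57 lower genes. With the slide trend removed r was 0.81, and with an offset of 0 as well there were 166 and 333 genes at r = 0.82. The array with pole cells in Cy3 alone gave 179 and 323. A size rule of 0.6 gave 174 and 305, a rule of 2 gave 9 and 8, and a rule on the mean alone 107 and 187. limma with the arrays as separate replicates, which measures only the spread between hybridisations if the extracts were the same, gave 107 and 187 at a log2 ratio of at least 1, with 840 genes of any size at an adjusted p under 0.05 and 1511 at an unadjusted one. The cause of these shifts was not tested, but some follow by construction. A looser or stricter size rule changes counts, and a rule on the mean alone keeps every gene of the main rule. An offset of 0 no longer draws dim log ratios toward 0. Median centring leaves any dye trend with signal in place, and the array medians under it had opposite signs. The limma counts equal those of the rule on the mean, so its p-value removed no gene of that size.

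The germ plasm median of 1.01 was 1.33 with the Feature Extraction log ratio and with its processed signals, 1.32 with an offset of 0, 1.08 without background subtraction, 1.19 in the value table, 0.92 with the mean of all probes, 0.93 with outlier spots kept, 1.34 with the slide trend removed at an offset of 0, and 1.24 as a mean over members. The heat shock median of 2.03 was 2.69, 2.68 and 2.67 under the first 3 of these, 2.48 in the value table and 2.67 with the slide trend removed at an offset of 0. The cellularisation median of -0.59 was -0.86 with the mean of all probes and -0.87 with outlier spots kept. The oxidative phosphorylation median turned from -0.05 to 0.02 with median centring. Of the values of other lists, 229 were counted as moved by less than the spread of the orientations, 58 by more and 1 as reversed. That last count does not hold every change of sign. The cytoplasmic ribosomal protein median of -0.09 was 0.02 on the array with pole cells in Cy3. On the array with pole cells in Cy5, the mitochondrial ribosomal protein median of -0.06 was 0.02 and the housekeeping median of 0.17 was -0.02. Of 128 named genes, the 54 past the size rule kept their sign under every alternative, at a median of 1.21 times the log2 size with an offset of 0. The size rule demands the same direction on each array, so they could not change sign on a single array, and this stability is partly fixed by their selection. Dim signals limit these results, since 0 of the genes past the size rule lay in the dimmest of 3 equal groups by average signal.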

Other observations

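Genes in the paragraphs on biology here were chosen after their values were seen, and the gene lists for insulators, Hsp90 cochaperones, TFIID and Mediator, the dorsal midline and later blastoderm genes were written after the genes past the size rule were seen. Tests written only after their result was seen were those of the heat shock genes, of gene content for the slide trend, and of background correction for the dorsal genes. Tests on list members not looked at before were written first, but the condition that members outside the dimmest of 3 equal groups of genes must also exclude a shift was added after the first results. The test of the slide trend on control spots was written before its result but after the trend was seen.

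No test of enrichment lies behind the way genes are grouped in this paragraph and the next. Among other genes higher in pole cells were wun2, a lipid phosphatase gene that acts in germ cell migration (log2 1.51), gwl, the Greatwall kinase (2.83-fold), stil (1.16) and CycJ (1.31). The transcription factor subunit genes Taf12L (1.82, with whole embryo RNA well above background on 1 of the 2 arrays) and Taf3 (1.74) were higher, as were the Hsp90 cochaperone genes p23 (1.74) and Pih1D1 (1.19), the cohesin loader Nipped-B (1.25) and Tif-IA, a factor for RNA polymerase I (1.34).

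Among lower genes, besides BEAF-32, Elba2 and Elba3, were M1BP (log2 -1.58), Elba1 (-1.57), su(Hw) (-1.25) and Cp190 (-1.19), so that all 3 Elba subunits were lower. Others were the nuclear envelope gene LBR (-1.45), the corepressor gene Sin3A (-1.44), the histone methyltransferase Set2 (-1.32), the heterochromatin protein gene HP1b (-1.28) and the Polycomb group gene Scm (-1.12), although other probes of Sin3A and Scm gave 0.18 and 0.05. Genes of DNA synthesis, Cdc45 (-1.32) and RnrS (-1.06), the Wnt pathway gene pygo (-1.62), the F-box genes ago (-1.38) and slmb (-1.19), and the maternal thioredoxin dhd (-1.24) were lower as well, with another probe of slmb at 0.04.

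Heat shock genes had the highest median of all lists, 2.03. The values argue against background correction and normalization, since the lowest median over 8 such alternatives was 2.03. They also argue against probes shared by the near-identical Hsp70 copies for Hsp23, whose lowest log2 ratio on either array was 1.64. The lowest for Hsp68 was 2.28, but whether its probe also takes up Hsp70 RNA was not examined, so its value does not decide this. Shared probes stay open for the list as a whole, as its 6 members other than Hsp70 copies had a median of 0.55. A stress response during dissociation and sorting may account for the pattern. It cannot be told apart from a property of pole cells, because the labels describe sorting for pole cells only. The immediate early, JNK and apoptosis list at the 67.4th percentile of random lists does not decide it. Hsp70 transcription or storage in pole cells in the intact embryo was not tested.

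Log ratios changed smoothly across the slide. If the genes placed in each region were the reason, medians of slide tiles would move together on both arrays as pole cells over whole embryos, but they correlated at r = -0.98 over 100 tiles. Positive control spots, which frame the slide and hold no fly gene, took no part in the fit of the trend, and their red over green followed the trend of the gene probes at r = 0.80 over 304 spots with pole cells in Cy5 (bootstrap limits 0.67 to 0.91) and 0.94 over 293 with pole cells in Cy3 (0.92 to 0.96). This is consistent with unequal hybridisation or scanning of the dyes across the slide. The control spots came from 2 probes. Their slopes on the trend of the gene probes were 3.06 with pole cells in Cy5 and 2.49 with pole cells in Cy3. The controls thus followed its direction but not its size. No biological explanation was tested for the trend across the slide.

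Several genes of the dorsal blastoderm had ratios above 0 in pole cells, led by ush (log2 1.11), peb (1.05) and Ance (0.85). The 9 noticed first had a median of 0.62, but they were noticed for their values, which raises it. Among other dorsally expressed genes of the dorsoventral list, Doc3 gave 0.09, dpp 0.04, zen2 -0.08 and tld -0.72. Lower by the size rule was tsg (-1.02). With the offset of 50, none of the 16 genes of the dorsal midline list was past the size rule. With an offset of 0, 4 were, and 5 with the slide trend removed as well. The median of the 9 ranged from 0.55 to 1.19 over 8 other background corrections and normalizations. Those alternatives use the same scans in which the 9 were high, so this does not decide whether processing was the source. Whether older embryos lay behind the pole cell RNA was put to 9 later blastoderm genes not looked at before. Their median was -0.13 (bootstrap limits -0.55 to 0.05, and -0.55 to -0.06 for the 7 brighter ones), under the 0.3 set beforehand. On each array alone it was 0.03 (-0.37 to 0.23) with pole cells in Cy5 and -0.49 (-0.85 to 0.07) with pole cells in Cy3. This met the bound set against older embryos but does not exclude them. Genes of the layer that forms the body could be low in sorted pole cells at any age. The 3 members noticed first for their values, left out of these 9, had a median of 0.91, and all 12 together had limits of -0.46 to 0.48. Cells of the dorsal midline sorted with the pole cells may still contribute: the 7 midline genes not looked at before had a median of -0.07 (-0.17 to -0.01), which met the bound set against this explanation, but several are dim, and the limits for the 4 brighter ones were -0.39 to 0.67. Expression of these genes in pole cells themselves also stays open and untested.

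As whole lists, which include the genes that prompted them, the medians were 0.32 for the dorsal midline genes, -0.05 for the later blastoderm genes, -0.31 for insulator and boundary factors, 0.23 for Hsp90 and its cochaperones and -0.03 for TFIID and Mediator subunits. The hypothesis that insulator factors are lower in pole cells as a group was left undecided by the 12 members not looked at before, whose median was -0.04 (bootstrap limits -0.31 to 0.09) against -1.58 for the 7 noticed first. The hypothesis that Hsp90 cochaperones are higher as a group was left undecided by 10 members, with a median of 0.06 (-0.23 to 0.30), whose upper limit lay at the bound of 0.3 and fell on either side of it until the number of bootstrap draws was raised to 200000. The hypothesis that TFIID and Mediator subunits are higher as a group was argued against by 36 members, with a median of -0.09 (-0.19 to 0.03). All 40 had limits of -0.16 to 0.10. MED26, Taf3 and Taf12L were thus higher although the list as a whole was not. These limits cover the spread between members on these arrays and not between replicates.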
